A study of Flaveria bidentis and Flaveria robusta with 100 samples.

How the data were processed

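The series holds RNA sequencing of mature leaves of 2 Flaveria species, the C4 plant F. bidentis and the C3 plant F. robusta. Per the labels, plants spent 36 days in a greenhouse and then 6 days in a growth chamber with 10 h of light at 22 °C and 14 h of dark at 20 °C (LD), before constant light (LL). Leaves were collected every 4 h through 2 LD days and 2 LL days and at the start of a day 3 in LL. Time points are named by regime, day and zeitgeber time (ZT, hours after lights on, or after subjective lights on in LL). Each species has 25 time points and each time point 2 biological replicates, which makes 100 libraries in 50 groups. Libraries were sequenced as single reads of 100 bp with 12 libraries per lane. The labels name CASAVA and the Arabidopsis build TAIR10 without giving their roles; the aligner, its parameters and the way reads were matched across species are not given in the sources used here.

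The deposited table lists 21869 Arabidopsis gene identifiers, of which 17834 carry a description and 15814 have a value above 0. The values used are reads scaled by the authors to a common library total (RPM) and averaged by the authors over the libraries of a time point (the authors' mean RPM), in steps of 0.5. The 50 columns of means sum to between 999417.5 and 1000090. Another 200 columns hold values per library under numbers that match no sample title, so they were not used here. No depth per library, spread between replicates or number of averaged libraries could therefore be used, and no interval for a single mean is given. All p-values measure the spread of time-point means around the fitted model, not the spread between plants.

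Values were analysed as log2(mean RPM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with trend and robust settings on). The 13563 genes with a mean of at least 1 RPM over the 50 means were tested, and p-values were adjusted over them by the Benjamini-Hochberg method with a threshold of 0.05. A rhythm was the F test of a cosine and a sine of 24 h beside a linear trend in elapsed time, fitted to 12 means in LD or 13 in LL. Sizes of rhythms are fitted peak-to-trough differences on the log2 scale, and peak hours carry delta-method errors. Differences in rhythm between species or regimes were the F test of the products of that factor with the cosine and sine. Mean levels were compared between species at matched time points. Light at night compared LL with LD at ZT12, ZT16 and ZT20, hours that are dark in LD, within each hour and within each species, and the difference between species was the product of species and regime. LL always followed LD, so regime cannot be told apart from day of sampling or plant age.

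A free-running period shared by the measured core clock genes was read from a grid of 18 to 32 h in steps of 0.25 h, with a jackknife over genes for its error and a two-sided permutation test of the difference between species with 100000 resamples. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 15 lists. The limma function fry, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes, was run beside it.

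Comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The 15 lists hold 212 genes, of which 170 were tested: core clock, clock output, C4 cycle, Calvin-Benson cycle, photorespiration, light harvesting, cyclic electron flow, starch metabolism, dark and starvation response, flavonoid and photoprotection, heat and wound stress, dividing cells, guard cells, vascular tissue and senescence. Any core clock or C4 cycle gene could be named. Of every other list the count is given with up to 4 members of smallest adjusted p and any member that went against its list. Beyond the lists, up to 5 genes per direction are named that passed the threshold, carry a description and reach 10 RPM in the higher group, by largest fold or, for rhythms, by smallest adjusted p. Gene symbols are those of the Arabidopsis genes to which the authors assigned the reads.

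The alternatives fixed beforehand were factors from a trimmed mean of M values (TMM, trimming 30% of M and 5% of A values, computed on the RPM values), a pseudocount of 0.1, no filter, a filter at 5 RPM, no linear trend, an added 12 h cosine and sine, a minimum ratio of 1.5 for rhythms or 2 for other changes, and LL from ZT12 of its day 1 only. Chosen after seeing the data were the omission of each time point in turn, the omission of 6 F. robusta time points whose composition stood apart, peak hours and list counts after TMM, ranges per day (also after TMM), peaks paired at random, the LL day comparisons at daylight hours (also after TMM), Fisher's exact test of lists among genes with a species difference in rhythm, pairs of genes with parallel profiles, and correlations of LL time points with LD hours. Fits were tested on simulated data: of 100 genes given a rhythm of 2 log2 units in LL, 93 were recovered in F. bidentis and 91 in F. robusta, and of 100 given 1 log2 unit, 63 and 37. Of 100 genes given a rhythm of 2 log2 units in F. bidentis alone, the test between species recovered 82 in LD and 80 in LL. With 1 log2 unit it recovered 23 and 6. The simulated rhythms were 24 h cosines of constant size, so these shares do not apply to rhythms that shrink during LL. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.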

Results

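Mature leaf transcripts were measured every 4 h in F. bidentis (C4) and F. robusta (C3) through 2 days of light and dark (LD) and 2 days of constant light (LL), to ask how the circadian clock and its targets differ between a C4 and a C3 species. Each of the 50 groups is the authors' mean RPM over the libraries of 1 time point, with 2 biological replicates per the labels. Depth and spread per library were not used here, so precision comes from the scatter of 12 LD or 13 LL means per species around each model. Scaling matters in these data: the total RPM of each mean is fixed, and TMM factors (which scale by the bulk of genes) ranged from 0.811 to 1.36 across means, with factors above 1 at ZT12, ZT16 and ZT20 of every LD day.

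Most core clock genes had large rhythms in LD in both species. The morning genes CCA1 and LHY, MYB factors that repress evening genes, peaked around dawn, with fitted peak-to-trough differences of 6.12 (SE 0.23) and 6.81 (SE 0.17) log2 units in F. bidentis and 6.00 (SE 0.23) and 6.75 (SE 0.21) in F. robusta. The pseudo-response regulators followed: PRR7 peaked at 7.68 h in F. bidentis and 7.69 h in F. robusta, and PRR3 at 7.74 and 7.92 h. The evening genes GI, LUX and TOC1, the last a repressor of CCA1 and LHY, peaked at 9.11, 11.2 and 12.9 h in F. bidentis and at 10.4, 10.8 and 12.8 h in F. robusta. The rhythm of TOC1 spanned 5.67 log2 units in F. bidentis and 3.66 in F. robusta, and that of FKF1, a blue light receptor, 6.33 and 5.08. Neither gene passed limma's test of a species difference in rhythm as deposited or after TMM (adjusted p = 0.0684 and 0.328 after TMM). TOC1 passed with an added 12 h term.

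Of the 22 measured core clock genes, 19 were rhythmic in F. bidentis and 20 in F. robusta (21 and 20 adjusted over the list alone; 17 and 19 after TMM). In F. bidentis ZTL, LKP2 and FIO1 did not pass (adjusted p = 0.0645, 0.166 and 0.0527), and in F. robusta LKP2 and CHE did not (adjusted p = 0.232 and 0.731). LKP2 passed in both species after TMM, and ZTL passed in F. bidentis with an added 12 h term. Among the 18 genes rhythmic in both species, the median peak difference (F. bidentis minus F. robusta) was -0.10 h, with a range from -1.77 to 3.65 h. The difference exceeded 2 standard errors for 5 genes. After TMM, 15 genes were rhythmic in both species, with a median of -0.18 h and a range from -5.63 to 2.13 h. Leaves were collected every 4 h, so differences under 1 h rest on the fitted curve.

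**Figure D1:**
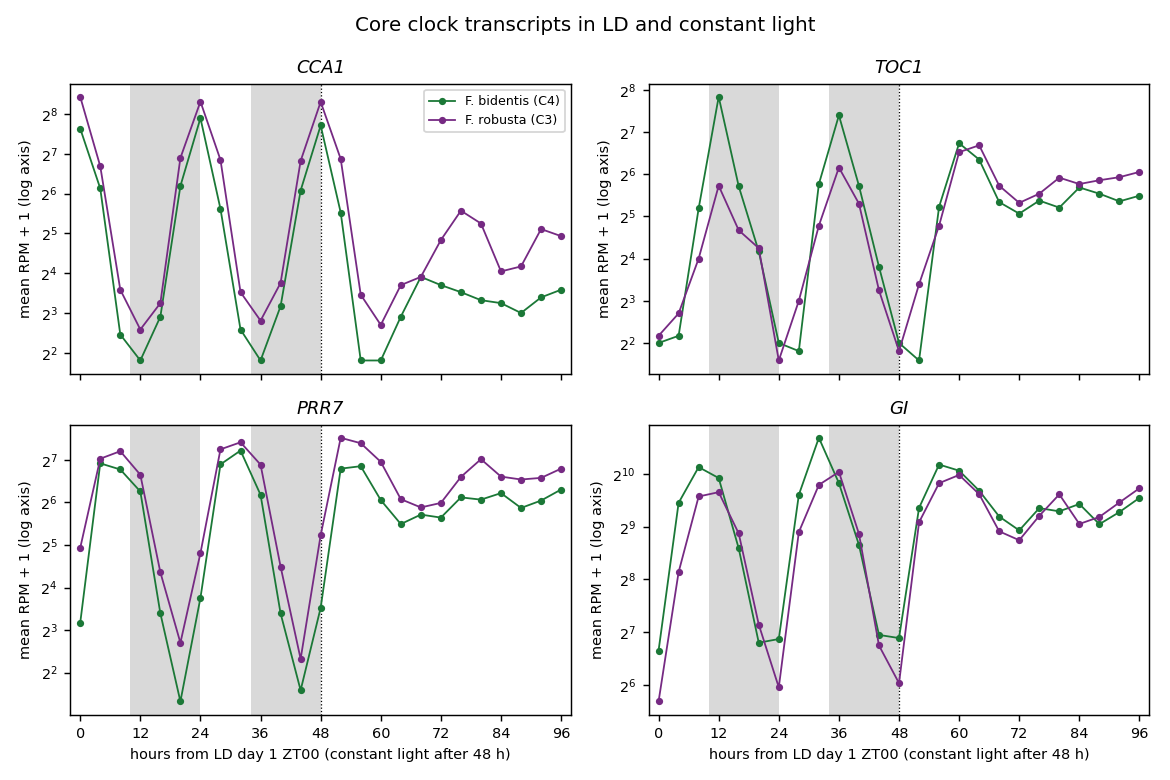
Mean RPM + 1 (log axis) of CCA1, TOC1, PRR7 and GI against hours from ZT00 of LD day 1 in F. bidentis (green) and F. robusta (purple), with each point the authors' mean of a time point and grey marking dark hours. The LD rhythm of TOC1 spanned 5.67 log2 units in F. bidentis and 3.66 in F. robusta, and did not pass the test of a species difference as deposited. Swings were small on LL day 2.

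All 7 measured clock output genes were rhythmic in both species, among them RVE1, a MYB factor of the auxin pathway (4.70 and 5.61 log2 units, peak at 21.5 and 21.2 h), and the RNA-binding protein gene GRP7 (5.29 and 4.71). All 11 light harvesting genes were rhythmic in F. bidentis and 10 in F. robusta; LHCB6 spanned 4.97 log2 units in F. bidentis and 4.42 in F. robusta. In starch metabolism 21 of 25 genes cycled in F. bidentis and 20 in F. robusta (22 and 21 adjusted over the list alone). The starch synthase gene GBSS1 peaked at 3.17 and 3.05 h, spanning 3.91 and 4.76 log2 units, while the phosphatase gene SEX4, which acts in starch breakdown, peaked at 12.1 and 12.6 h. PGR5, needed for cyclic electron flow around photosystem I, spanned 4.45 and 5.19 log2 units; 7 and 6 of the 9 genes of its list were rhythmic.

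In the Calvin-Benson cycle 10 and 9 of 14 genes were rhythmic (11 and 8 adjusted over the list alone), among them RCA (Rubisco activase; 2.03 and 1.67 log2 units). In photorespiration 16 and 11 of 17 were (17 and 7 after TMM), and in the C4 cycle list 13 and 19 of 26 (15 and 20 after TMM). The flavonoid and photoprotection list had 5 and 8 of 8 rhythmic genes, with ELIP1, an early light-induced protein gene, at 4.24 and 3.99 log2 units. The dark and starvation response list had 2 and 6 of 7 (1 and 5 after TMM).

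Over all genes, limma called 9130 of 13563 genes (67.3%) rhythmic in LD in F. bidentis and 8875 (65.4%) in F. robusta. The 2 sets shared 6686 genes, against 5974.2 if independent. Among shared genes the median peak difference was -0.32 h, and 71.1% peaked within 2 h of each other, against 31.4% when peaks of these genes were paired at random. After TMM the sets shared 3280 genes (2311.4 if independent), of which 67.4% peaked within 2 h (18.8% if paired at random). The genes with the smallest adjusted p beyond the lists included a B-box zinc finger gene (AT2G21320; 6.44 log2 units, peak at 23.5 h) and the sulfate transporter genes AT3G12520 and AT5G13550 in F. bidentis. In F. robusta they included the ferric reductase FRO6 (AT5G49730; 4.74 log2 units, peak at 22.6 h) and a hydrolase gene of the haloacid dehalogenase family (AT2G41250; 7.43 log2 units). These totals depended on the scaling: after TMM the counts were 5532 and 5667, and the share of rhythmic genes peaking nearest ZT12 or ZT16 went from 72.5% to 27.9% in F. bidentis and from 72.9% to 33.7% in F. robusta.

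Genes of the C4 cycle stood out where rhythms differed between the species in LD. The NADP-malic enzyme genes, whose product releases CO2 from malate in C4 leaves of this type, cycled in F. robusta and spanned little in F. bidentis: NADP-ME1 had a peak-to-trough difference of 2.52 log2 units in F. robusta against 0.28 in F. bidentis (adjusted p = 3.6e-06), NADP-ME2 2.73 against 0.40 and NADP-ME4 2.35 against 0.28. NADP-MDH, the malate dehydrogenase gene of chloroplasts, spanned 1.87 against 0.45 (adjusted p = 0.000115), and PPDK, whose enzyme regenerates phosphoenolpyruvate, 1.77 against 0.12 (adjusted p = 0.0395; 1.26 against 0.58 after TMM). The phosphoenolpyruvate carboxylase gene PPC1 peaked at 2.57 h in F. bidentis and 19.4 h in F. robusta, spanning 0.73 against 1.26 log2 units (adjusted p = 0.00267); after TMM the spans were 1.29 against 1.07, so which species had the larger one turned. The kinase gene PPCK2 peaked at 3.79 and 11.7 h, and the PPDK regulator gene RP1 at 12.2 and 15.9 h. DIT2.2, a dicarboxylate transporter gene, had the larger span in F. bidentis (1.27 against 0.54), and the pyruvate transporter gene BASS2 spanned 0.96 against 1.32; both lost their call after TMM (adjusted p = 0.0636 and 0.0884). With an added 12 h term PPDK and BASS2 lost theirs, and without F. robusta LD2 ZT12 and ZT16 PPCK2 and BASS2 did.

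In all, 11 of 26 C4 cycle genes differed in rhythm (13 adjusted over the list alone; 10 after TMM, of which 9 shared), or 42.3% against 8.97% of other genes (Fisher's exact test, two-sided, adjusted p = 0.000101 over 15 lists; 0.00321 after TMM). Photorespiration followed with 7 of 17 genes (8 adjusted over the list alone; 41.2% against 8.99%, adjusted p = 0.00312; 0.0503 after TMM), and no other list had an adjusted p under 0.05. Several C4 cycle entries ran in parallel and may share reads of the same Flaveria gene: over 25 means, Pearson's r was 0.989 and 0.994 between PPC1 and PPC2, 0.972 and 0.998 between NADP-ME1 and NADP-ME4, and 0.946 and 0.992 between NADP-ME2 and NADP-ME4, in F. bidentis and F. robusta. The same held for clock entries, with 0.994 and 0.997 between CCA1 and LHY, 0.993 and 0.983 between PRR3 and PRR7 and 0.982 and 0.986 between PRR5 and PRR9. It held too for SBE2.1 and SBE2.2 of starch metabolism (0.997 and 0.979) and for the sulfate transporter genes AT3G12520 and AT5G13550 (0.998 and 0.980), so counts of these genes may rest on fewer independent entries.

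**Figure D2:**
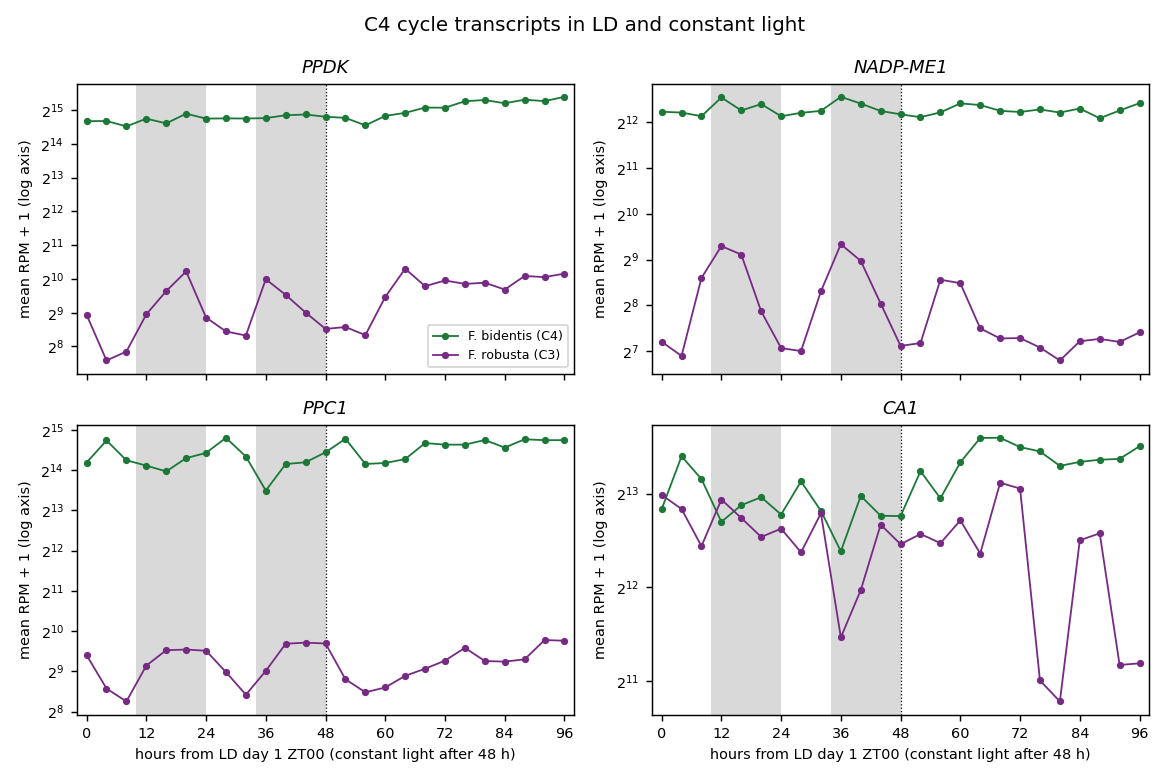
Mean RPM + 1 (log axis) of PPDK, NADP-ME1, PPC1 and CA1 against hours from ZT00 of LD day 1 in F. bidentis (green) and F. robusta (purple), each point the authors' mean of a time point, grey marking dark hours. NADP-ME1 had a fitted LD span of 2.52 log2 units in F. robusta and 0.28 in F. bidentis.

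Photorespiration genes differed in both directions. SHM1, the serine hydroxymethyltransferase gene, spanned 0.98 log2 units in F. bidentis and 0.13 in F. robusta, the glycine decarboxylase gene GLDP2 1.94 and 0.50, LPD1 1.03 and 0.54, and the aminotransferase gene SGAT 1.38 and 2.25. In starch metabolism 5 of 25 genes differed (6 adjusted over the list alone), with larger spans in F. bidentis for the glucan, water dikinase gene GWD1 (3.64 against 2.63), the debranching enzyme gene ISA1 (3.49 against 1.73) and the branching enzyme genes SBE2.2 (1.94 against 0.70) and SBE2.1 (1.79 against 0.73). In the Calvin-Benson cycle FBA1 (aldolase; 0.55 against 2.15), RCA and GAPB differed, GAPB not after TMM. NDHM and NDHO of the cyclic electron flow list differed (NDHO not after TMM), as did RVE7 of the clock outputs and LHCB7 of light harvesting. With an added 12 h term SBE2.1, GAPB and NDHO lost their calls, and without the same 2 F. robusta means ISA1 and NDHO did. No gene of the flavonoid or dark response lists passed (3 of the dark response list adjusted over the list alone), though DIN10 of the dark response list did after TMM (adjusted p = 0.0472).

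No core clock gene differed in rhythm between the species in LD by limma's adjusted p; the smallest were LHY (0.0627), TOC1 (0.0769), RVE6 (0.087) and CHE (0.0929). After TMM, LHY (adjusted p = 0.0291) and CHE (0.0445) passed, and with an added 12 h term TOC1 and RVE6 did. Of 100 simulated genes with a species difference of 1 log2 unit in LD, this test recovered 23. A gene that did not pass is therefore not shown to have equal rhythms. Over all genes 1225 differed (3327 at unadjusted p under 0.05). Beyond the lists, the smallest adjusted p belonged to genes with larger spans in F. bidentis, such as AT4G17360 (a formyl transferase; 2.86 against 0.81 log2 units) and AT3G12520 (sulfate transporter; 3.85 against 1.12), and to genes with larger spans in F. robusta, such as AT1G26220 (an acyltransferase; 0.41 against 4.18) and the histidine kinase gene AT2G17820 (1.27 against 2.81).

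The swings of clock genes were small on LL day 2. At ZT20 of LL day 1 the rise of CCA1 before dawn was smaller than in LD, with 14 RPM against 72 and 66.5 on the LD days in F. bidentis and 14 against 118 and 112 in F. robusta. The median range of the 22 core clock genes over 24 h was 4.00, 4.30, 3.23 and 0.55 log2 units on LD day 1, LD day 2, LL day 1 and LL day 2 in F. bidentis, and 3.53, 4.21, 3.09 and 0.98 in F. robusta. After TMM the medians on LL day 2 were 0.50 and 0.56, so the larger value in F. robusta nearly vanished; 3 of its 6 means on that day are of unusual composition. The range on LL day 2 was smaller than on either LD day for 22 of 22 genes in F. bidentis and 19 of 22 in F. robusta (20 and 20 after TMM). Light harvesting genes went from a median of 3.09 on LD day 2 to 0.52 on LL day 2 in F. bidentis and from 4.35 to 1.08 in F. robusta (0.68 and 1.54 on LL day 2 after TMM). These ranges carry no test, and each is the highest minus the lowest of 6 means. Hours ZT00 to ZT08 of LL day 1 were lit in LD too, so the range on that day does not show that rhythms persisted in constant light.

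By limma, 0 genes were rhythmic over LL in either species after adjustment, with 2612 in F. bidentis and 1788 in F. robusta at unadjusted p under 0.05 where chance gives 678.2. Fitted LL spans were 2.60 (SE 0.76) and 2.77 (SE 0.77) log2 units for CCA1, 2.97 and 3.27 for LHY and 2.27 and 1.79 for TOC1 in F. bidentis and F. robusta. Adjusted over the list alone, 1 core clock gene was rhythmic in F. bidentis (ELF4) and 9 in F. robusta (CCA1, LHY, PRR3, PRR5, PRR7, PRR9, FKF1, JMJD5 and LNK1). Clock output genes gave 7 and 6, starch genes 8 and 2, cyclic electron flow genes 1 and 3, and Calvin-Benson and heat stress genes 0 and 2 each. These fits include ZT00 to ZT08 of LL day 1, which followed an LD night and were lit in LD too. The LL spans and the calls over single lists therefore do not show that rhythms persisted in constant light. In F. bidentis, 15 genes were called when LL2 ZT08 was left out. Rhythms in LL differed between the species for 0 genes (1033 at unadjusted p under 0.05, and 5 called without F. bidentis LL2 ZT08). Of 100 simulated genes with a species difference of 1 log2 unit in LL, this test recovered 6. The count of 0 therefore does not show equal rhythms.

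**Figure D3:**
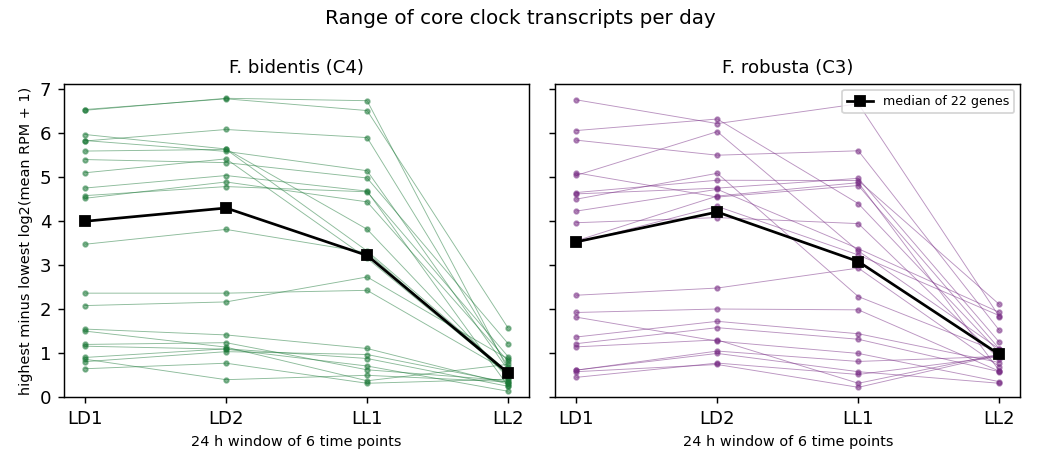
Range of each measured core clock gene (highest minus lowest log2(mean RPM + 1) of 6 means) per 24 h window in F. bidentis (left) and F. robusta (right), thin lines being genes and black squares their median. The median on LL day 2 was 0.55 log2 units in F. bidentis and 0.98 in F. robusta as deposited, and 0.50 and 0.56 after TMM.

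The shared free-running period of the 22 core clock genes in LL was 22.5 h (jackknife SE 0.33) in F. bidentis and 22.75 h (SE 1.12) in F. robusta. The difference of -0.25 h was not distinguishable from 0 (two-sided permutation test, p = 0.905). The estimates depended on the model. Without the linear trend they were 21.75 and 27.25 h (difference -5.5 h, permutation test, p = 0.276), and after TMM 22.5 and 25.75 h (difference -3.25 h, permutation test, p = 0.104). With LL from ZT12 of day 1 only they became 32 h, the edge of the grid, and 19.75 h (difference 12.25 h, permutation test, p = 0.205), so no period is established here for either species.

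The clock genes PRR3, PRR7 and LNK1 were called in both species when rhythms in LD were compared with those in LL, though the calls as a whole depended on single means. In F. bidentis PRR5 and PRR9 did not pass (adjusted p = 0.235 and 0.306). In that species 63 genes changed (3239 at unadjusted p under 0.05), among them the core clock genes PRR3 (5.52 log2 units in LD, 1.21 in LL), PRR7 (5.84 and 1.32) and LNK1 (5.94 and 1.91), the light harvesting genes LHCA1 and LHCB4.2, and PPT2, PGR5, GBSS1 and LSF1. Adjusted over the list alone, 11 core clock, 7 clock output and 11 light harvesting genes changed. In F. robusta 3785 genes changed, among them 10 of 22 core clock genes (12 adjusted over the list alone; 4 after TMM), 7 of 7 clock output genes (4 after TMM) and 10 of 11 light harvesting genes (7 after TMM). They included 8 C4 cycle genes (2 after TMM), such as NADP-ME2 (2.73 in LD, 0.59 in LL; not after TMM), and zeaxanthin epoxidase (AT5G67030; 3.66 and 0.63). The sets shared 38 genes (17.58 if independent).

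Neither of these counts was stable. In F. bidentis it ran from 0 without LD1 ZT16 to 1844 without LL1 ZT00, and every single omission but that of LD2 ZT04 moved it by over 1.5 times. In F. robusta it was 492 after TMM and 0 without 4 LL means of unusual composition; single omissions gave 2491 (LD1 ZT16), 2394 (LD2 ZT00), 2289 (LD2 ZT08), 6046 (LL1 ZT16), 2163 (LL1 ZT20), 661 (LL2 ZT04), 2105 (LL2 ZT08), 1337 (LL2 ZT16) and 1727 (LL3 ZT00).

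C4 cycle transcripts were far higher in F. bidentis than in F. robusta throughout LD. PPDK stood at 27395 RPM against 566, a difference of 5.79 (SE 0.19) log2 units over 12 matched time points, and PPC1 at 5.10 (SE 0.17) log2 units higher. AMK2, an adenylate kinase gene of the chloroplast, was higher by 4.74 (SE 0.08), NADP-ME1 by 4.15, BASS2 by 3.95, NADP-MDH by 3.57, the aspartate aminotransferase gene ASP5 by 3.36, and the phosphoenolpyruvate transporter gene PPT1 by 2.92. CA1, the carbonic anhydrase gene, was higher by 0.37, a call lost without F. robusta LD2 ZT12 and ZT16. In total 20 of 26 genes were higher and 3 lower: NAD-ME1 (-1.08), NAD-ME2 (-0.97) and PCK1 (-1.13), which serve other C4 decarboxylation routes. ASP1 (-0.04, with its sign turning without those 2 means), ASP2 (-0.17) and PPCK2 (0.42) did not pass.

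Photorespiration ran the other way, with 16 of 17 genes lower in F. bidentis. The ferredoxin-dependent glutamate synthase gene GLU1 differed by -2.20 (SE 0.10) log2 units, the glycine decarboxylase genes GLDT and GLDH3 by -1.99 and -1.64, and LPD1 by -1.96; only the mitochondrial carrier gene BOU was higher (0.66). By camera the C4 cycle list was higher (adjusted p = 4.4e-07; adjusted p = 0.00595 with an estimated correlation) and photorespiration lower (adjusted p = 5.48e-08; adjusted p = 0.00595 with an estimated correlation). By fry their adjusted p were 3.77e-13 and 1.67e-12.

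**Figure D4:**
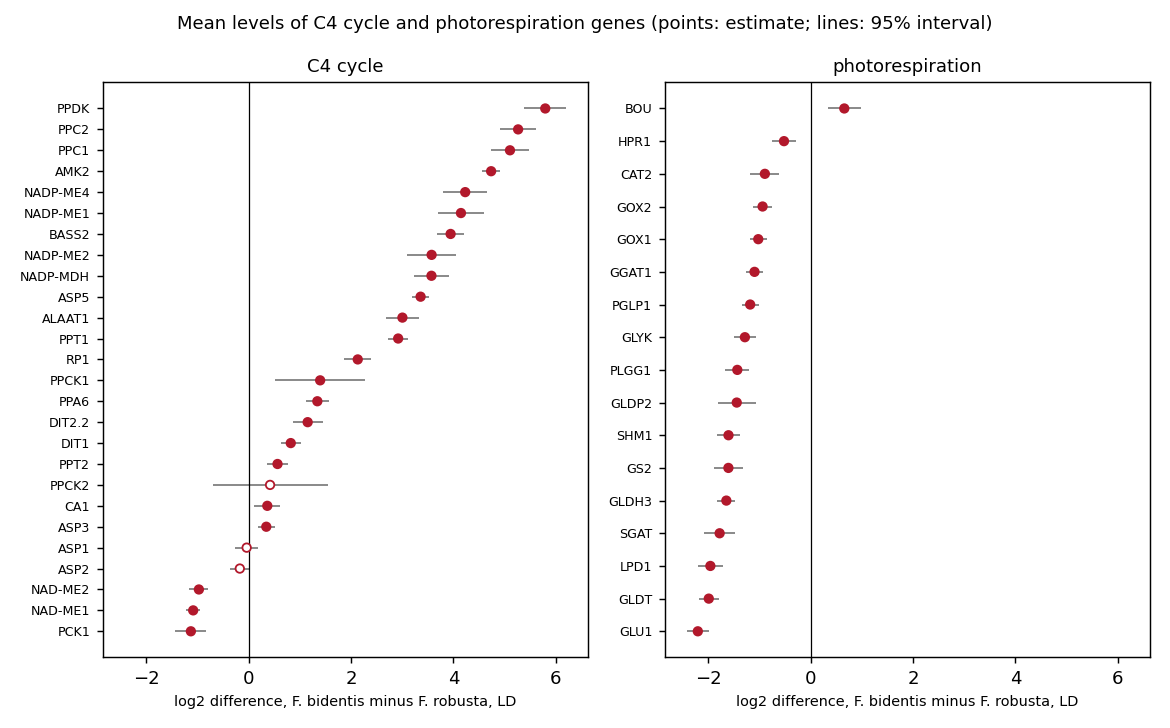
Difference in mean LD level (log2, F. bidentis minus F. robusta) of measured C4 cycle and photorespiration genes, with points the estimate over 12 matched time points, lines the 95% interval and filled points past the threshold. PPDK lies at 5.79 and GLU1 at -2.20; BOU is the photorespiration gene above 0.

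Cyclic electron flow genes were higher in F. bidentis in 9 of 9 cases, with the NDH complex genes NDHN at 2.03, PNSB1 at 1.90 and NDHM at 1.46 log2 units (camera adjusted p = 8.51e-06; adjusted p = 0.0417 with an estimated correlation). The 7 clock output genes were all higher, led by the flowering regulator CO (1.16) and CDF3 (0.87; camera adjusted p = 0.0093; adjusted p = 0.0488 with an estimated correlation). In the Calvin-Benson cycle 2 genes were higher and 8 lower (7 after TMM), with the Rubisco small subunit gene RBCS1A at -1.83, RCA at -1.92 and, against the list, CP12-2 at 1.06 and TPI at 0.26 (camera adjusted p = 0.0458; adjusted p = 0.492 with an estimated correlation; 0.104 after TMM). Flavonoid genes were lower in 7 of 8 cases, such as CHS (chalcone synthase; -1.68) and F3PH (-2.22; camera adjusted p = 0.0093; adjusted p = 0.403 with an estimated correlation). The 7 dark and starvation genes were all higher, with the asparagine synthetase gene ASN1 at 1.97 (camera adjusted p = 0.027; adjusted p = 0.403 with an estimated correlation).

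Other lists went both ways. The core clock had 9 genes higher and 7 lower, with RVE8 at 0.85 and ELF4 at 0.80, and FIO1 at -1.15, CCA1 at -0.77 and PRR7 at -0.77 (camera adjusted p = 0.84, higher; fry lower, adjusted p = 0.776). Light harvesting had 4 higher and 2 lower genes, the photosystem I antenna gene LHCA4 at 1.45 and LHCB7 at -1.58, and starch metabolism 10 and 4, with GBSS1 at 1.47 and SS1 at -0.87. Over all genes 4384 were higher and 4405 lower in F. bidentis in LD. Beyond the lists, the peptidase gene AT4G17830 stood at 149.8 RPM in F. bidentis and was listed at 0 in F. robusta, and the flowering regulator SPL9 (AT2G42200) was higher by 5.19 log2 units. The permease gene AT5G19500 was listed at 0 in F. bidentis, and the oligopeptide transporter gene AT5G64410 differed by -4.57. Reads of both species were assigned to Arabidopsis genes, so a gene at 0 in 1 species may reflect that assignment.

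In LL 22 C4 cycle genes were higher and 3 lower, 16 of 17 photorespiration genes lower and 9 of 9 cyclic electron flow genes higher. PPDK was higher by 5.47 and NADP-ME1 by 4.83 log2 units. By camera the C4 cycle kept its call with an estimated correlation (adjusted p = 0.00518), while photorespiration, cyclic electron flow and clock output did not (adjusted p = 0.15 each). Light harvesting had 8 genes higher and 1 lower, with LHCA4 at 1.85 (camera adjusted p = 0.0256; adjusted p = 0.558 with an estimated correlation; 0.189 after TMM), and flavonoid genes 1 higher and 7 lower (adjusted p = 0.0256; adjusted p = 0.554 with an estimated correlation). Starch metabolism had 9 higher and 6 lower, with a median of -0.01 and a mean of 0.17 log2 units; relative to the median of all genes its median was 0.13. The Calvin-Benson cycle had 3 and 7 (3 and 4 after TMM), the core clock 4 and 10 (7 and 8 after TMM) and clock output 6 and 0. Over all genes 3521 were higher and 5668 lower with a median shift of -0.13 log2 units, and 4786 and 4873 after TMM. LD and LL shared 3013 higher genes (1138.1 if independent) and 4027 lower genes (1840.9), with 44 in opposite directions.

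At the hours that are dark in LD, flavonoid and photoprotection genes were higher in LL in both species, and light harvesting genes were called in F. bidentis alone. With an estimated correlation the flavonoid list was called in F. robusta (adjusted p = 0.0366) and not in F. bidentis (0.0677), and light harvesting in neither (0.106 in F. bidentis, 0.127 in F. robusta). At ZT12 to ZT20, chalcone synthase (CHS) rose by 2.03 (SE 0.35) log2 units in F. bidentis and 1.80 (SE 0.31) in F. robusta, and the flavonol synthase gene FLS1 by 1.78 and 1.36; ELIP1 rose in both species, by 3.30 in F. bidentis. In F. bidentis all 11 light harvesting genes rose, among them LHCB1.2 by 1.67 and LHCB4.2 by 1.11, while 0 of 11 passed in F. robusta by limma. The list median was above 0 in F. robusta too (0.78 log2 units, against 1.11 in F. bidentis). No light harvesting gene passed the test of this response between species, so no species difference is shown.

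ZT00 to ZT08 of LL day 2 were compared with LD after seeing the data. These hours were lit in LD too, from lights on at ZT00. LD leaves at ZT00 had just passed 14 h of dark and LL day 2 leaves had not, so light history still differed. Here 5 of 8 flavonoid genes were higher than in LD in F. bidentis and 8 of 8 in F. robusta (4 and 7 after TMM), CHS by 1.77 and 2.08 log2 units. Light harvesting genes were lower there, 8 of 11 in F. bidentis and 10 of 11 in F. robusta (7 and 10 after TMM), LHCB6 at -1.56 and -2.56. In F. robusta these values rest on 3 LL means, of which LL2 ZT04 and LL2 ZT08 are of unusual composition. At the same hours of LL day 1, 0 genes passed in either species by limma (254 in F. bidentis and 747 in F. robusta at unadjusted p under 0.05). Light at night was not separated from weaker rhythms in LL, from time in LL, from age or from the cooler dark hours of LD.

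In the clock at ZT12 to ZT20, PRR3 rose by 2.36 and 2.42, PRR7 by 2.21 and 1.87, LNK1 by 2.17 and 1.74, while PRR5 and PRR9 also rose in both, by 1.08 and 0.94 in F. bidentis; CCA1 (-0.62 and -0.41) and LHY (-0.56 and -0.58) did not pass. In all, 6 core clock genes rose and 6 fell in F. bidentis (6 and 3 after TMM), against 6 and 2 in F. robusta (6 and 0 after TMM). ELF3 (-0.88 and -0.54) and LWD1 (-0.86 and -0.54) were lower as deposited. These values include a shift of the median of all genes by -0.21 in F. bidentis and -0.19 in F. robusta, which TMM removed; in F. robusta the ELF3 and LWD1 calls were lost after TMM. Without LD2 ZT12 and ZT16, 2 F. robusta means of unusual composition, the F. robusta calls of FLS1, PRR3, PRR7 and LNK1 were lost, as were those of PPCK1, PPT2, NADP-ME2 and BOU given below.

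In F. bidentis the C4 cycle list had 16 genes higher and 1 lower in light at night: the carboxylase kinase genes PPCK1 and PPCK2 rose by 2.73 and 2.46 log2 units, DIT1 by 1.06, AMK2 by 0.91, PPT1 by 0.78 and CA1 by 0.65, while PCK1 fell by 0.63. In F. robusta 4 rose, among them PPCK1 by 1.47, PPT2 by 1.42 and PPT1 by 0.81, and 3 fell: NADP-ME1 by 1.28, NADP-ME2 by 1.24 and NADP-ME4 by 1.22 (8 genes passed adjusted over the list alone). In F. bidentis 8 of 8 flavonoid genes, 6 of 14 Calvin-Benson genes (12 after TMM), and 6 of 9 cyclic electron flow genes (9 after TMM) rose. Starch metabolism had 5 higher and 7 lower, with LSF1 at -0.99 and BAM4 at -0.81 (13 and 4 after TMM), and photorespiration 2 higher and 3 lower (9 and 0 after TMM). In F. robusta 5 flavonoid genes (8 adjusted over the list alone), 3 starch genes including the branching enzyme gene SBE2.2 (0.59), and BOU of photorespiration rose; 0 light harvesting, Calvin-Benson and cyclic electron flow genes passed by limma.

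Camera placed 7 lists higher in F. bidentis. The C4 cycle (adjusted p = 1.07e-12; adjusted p = 0.0117 with an estimated correlation) and the Calvin-Benson cycle (3.04e-07; adjusted p = 0.0126 with an estimated correlation) held. Lost were light harvesting (2.46e-12; adjusted p = 0.106 with an estimated correlation), flavonoid (8.39e-11) and cyclic electron flow (1.81e-08; adjusted p = 0.0677 with an estimated correlation for both), starch metabolism (0.00241; adjusted p = 0.141 with an estimated correlation) and photorespiration (0.0149; adjusted p = 0.415 with an estimated correlation). In F. robusta it placed 8 higher, of which flavonoid (9.21e-15) and starch metabolism (0.000154) held (adjusted p = 0.0366 with an estimated correlation for both). Light harvesting, Calvin-Benson cycle and photorespiration (2.78e-08, 3.9e-08 and 5.51e-07) had adjusted p = 0.127 with an estimated correlation, the C4 cycle (0.00401) adjusted p = 0.124, and the core clock (5.82e-05) and cyclic electron flow (0.00297) adjusted p = 0.218. Median, mean and test differed in sign for starch metabolism in F. bidentis (median 0.15, mean -0.05) and for the core clock in F. bidentis (median -0.30, mean 0.16) and F. robusta (median -0.02, mean 0.37). Camera also placed clock output higher without calling it, with medians of -0.32 and -0.02 and means of -0.29 and -0.18 in F. bidentis and F. robusta, and dividing cells in F. bidentis (median -0.11) and F. robusta (median 0.05, mean -0.08); camera compares with other genes, whose median was below 0.

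By fry, which asks for a change against 0, the F. bidentis calls for photorespiration (adjusted p = 0.866) and starch metabolism (lower, 0.822) were not shared. In F. robusta fry called flavonoid alone (adjusted p = 0.015); starch metabolism had 0.204, light harvesting, Calvin-Benson cycle and photorespiration 0.181 each, core clock and cyclic electron flow 0.498 each, and the C4 cycle 0.831 (lower).

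**Figure D5:**
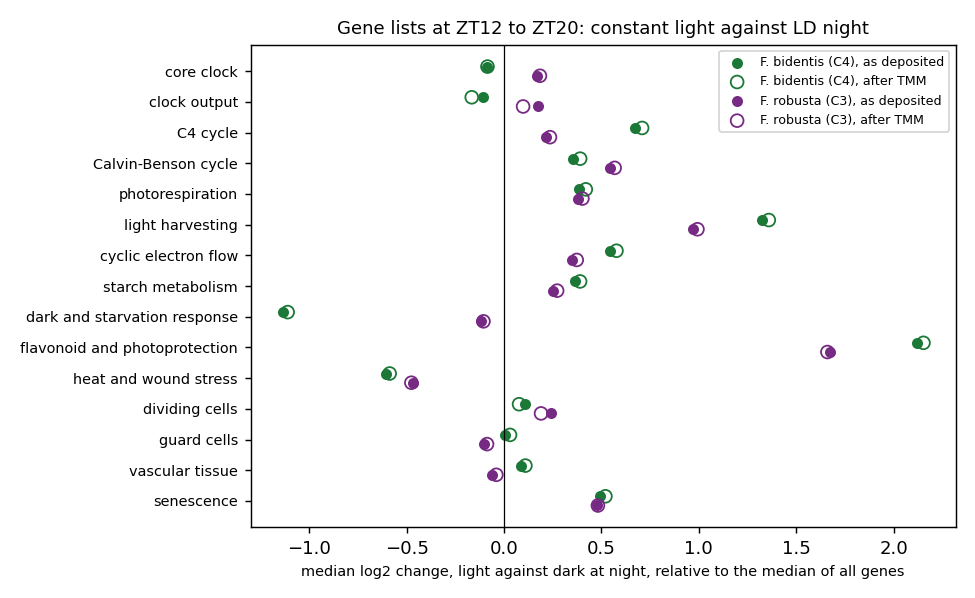
Median log2 change of each gene list between LL and LD at ZT12 to ZT20, relative to the median of all genes, in F. bidentis (green) and F. robusta (purple), as deposited (filled) and after TMM (open). The flavonoid and photoprotection list lies at 2.12 in F. bidentis and 1.67 in F. robusta, and light harvesting at 1.32 and 0.97.

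Over all genes, light at night changed 5555 genes in F. bidentis (751 higher, 4804 lower; 2095 and 1997 after TMM) and 856 in F. robusta (176 and 680; 351 and 205 after TMM), with 113 higher genes (9.75 if independent) and 495 lower genes (240.9) in both, and 8 in opposite directions. Among genes beyond the lists, AT5G67480 (BTB and TAZ domain protein 4) rose by 2.01 in F. bidentis and 2.66 in F. robusta, and the glucuronokinase gene AT3G01640 fell by 2.84 and 2.385. The tonoplast dicarboxylate transporter gene AT5G47560 fell by 2.55 in F. robusta, and its night mean in F. bidentis was lower in LL too (6.333 against 36.83 RPM). The F. robusta count depended on single means: without LD1 ZT12 it was 560, without LD1 ZT16 201, LD2 ZT16 266, LL1 ZT16 291, LL1 ZT20 387, LL2 ZT12 310, LL2 ZT16 131 and LL2 ZT20 2676.

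The response to light at night differed between the species for 140 genes, 38 of them more positive in F. bidentis and 102 more negative (1665 at unadjusted p under 0.05). NADP-ME1 differed by 1.16 (SE 0.24) log2 units, NADP-ME2 by 1.04 and ASP5 by 0.67, and NADP-ME4 also passed, with 10 C4 cycle genes adjusted over the list alone. The NADP-ME genes spanned little in F. bidentis in LD but cycled in F. robusta, where NADP-ME1 peaked at 12.9 h after TMM. A weaker rhythm in LL would lower them at ZT12 to ZT20 in F. robusta alone. The comparison cannot separate that from a response to light. MCCA, a gene of leucine breakdown in starved leaves, differed by -1.19, GLDP2 by -0.92, GLU1 by -0.66 (lost after TMM) and the starch gene BAM4 by -0.69 (lost after TMM). No core clock, light harvesting or flavonoid gene passed by limma. Beyond the lists, the CP12 gene AT1G76560 (1.56) and the zinc finger gene AT2G19810 (-2.62) were among those with the largest differences. After TMM 273 genes differed, and the count was 92 without F. bidentis LD1 ZT12, 86 without LD2 ZT16, 91 without LL1 ZT20, 89 without LL2 ZT12, and 218 without F. robusta LL1 ZT20.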

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

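The test of a copy with the F. robusta rhythm was chosen after the result was seen; the other tests were set beforehand. These results are returned to here because a comparison of species or regimes called genes: rhythms differing between species in LD (1225 genes), light at night differing between species (140), and rhythms differing between regimes in F. bidentis (63) and F. robusta (3785).

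Each comparison was repeated over 100 splits of the time points, the real one included. For rhythms between species in LD, 1 split of 100 called as many genes as the real one (1225, highest other 84), and for levels 1 did in LD (8789, highest other 2830) and 1 in LL (9189, highest other 7690). The same held for light at night in F. bidentis (1 split, 5555, highest other 849) and for its species difference (1 split, 140, highest other 1). For these, no other split tried called as many genes. The splits shuffle time-point means and hold no spread between replicates, so they cannot exclude chance differences between plants. For rhythms between species in LL the real count was 0, so all 100 splits reached it by construction (highest other 3) and the splits decide nothing. For light at night in F. robusta 2 splits did (856, highest other 2281), as for regimes in F. bidentis (2 splits; 63, highest other 87) and F. robusta (2 splits; 3785, highest other 4800). A share of 2 in 100 is under the limit of 5 set beforehand. Yet another split called more genes than the real one in each, and why was not tested. The regime counts also fell to 0 without F. bidentis LD1 ZT16 and without 4 F. robusta LL means. Chance is therefore not excluded for these results.

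C4 cycle genes such as NADP-ME1 and PPDK, with a smaller peak-to-trough ratio in F. bidentis than in F. robusta, may swing less relative to their level in the C4 species. Over the 9 such genes the authors' scaling stays undecided by the limits set beforehand, because the genes split. After TMM 5 of them still differed this way (NADP-ME1, NADP-ME2, NADP-ME4, NADP-MDH and PPDK), so scaling by TMM did not remove their difference. PPC1, PPC2 and PPCK2 had the larger span in F. bidentis after TMM, and BASS2 lost its call (limma adjusted p = 0.0884). The spans after TMM were 0.30 against 2.02 log2 units for NADP-ME1 and 0.58 against 1.26 for PPDK. After TMM, PPDK (limma adjusted p = 0.0116), NADP-MDH, PPC1, PPC2 and BASS2 were rhythmic in F. bidentis, so they were not flat there. NADP-ME1 (adjusted p = 0.25), NADP-ME2 and NADP-ME4 did not pass. PPCK2 did not pass either (adjusted p = 0.0643), but it was not flat, with a span after TMM of 3.40 log2 units against 2.86 in F. robusta. A rhythmic copy hidden under a higher flat level is also open: the median ratio of the LD range in RPM, F. bidentis over F. robusta, was 3.80, which under the prediction written beforehand would have favoured it, but it was called undecided after the value was seen, because scatter around a higher level alone widens a range. A copy with the F. robusta rhythm in RPM beside a flat copy was left out for 1 gene, BASS2, and stays undecided. At the F. robusta peak hour, NADP-ME1 had a component of 502.8 RPM in F. bidentis (interval 81.98 to 923.6). Its F. robusta amplitude was 272 RPM, so a rhythm of that size was not excluded. For NADP-ME2 and NADP-ME4 the components were 467.5 (104.4 to 830.7) and 576.3 (46.36 to 1106.3), against amplitudes of 282.2 and 292.8. The intervals of PPC1, PPC2, PPDK, PPCK2 and NADP-MDH held both the amplitude and 0, so they decide nothing.

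Light at night called more genes in F. bidentis than in F. robusta, and this difference in counts may come from precision or from size of effect. The median standard error in F. robusta was 1.298 times that in F. bidentis, the larger spread between time-point means being undecided by the limits set. The median absolute change in F. robusta relative to the median of all genes was 0.748 times that in F. bidentis, so smaller light effects are undecided too. In F. robusta that change (0.158 log2 units) was close to the median standard error (0.161), so noise is part of it. The F. robusta count also depended on single means, from 131 without LL2 ZT16 to 2676 without LL2 ZT20.

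The flattening of core clock genes such as CCA1 and PRR7 on LL day 2 could come from the authors' scaling, but after TMM the ratio of ranges on LL day 2 over LD was at most 0.150, which argues against it. Levels near the floor of the log scale are argued against for the list as a whole by a median core clock level of at least 19.4 RPM on that day. That median covers all measured core clock genes, also those with small rhythms. It cannot decide for single genes such as CCA1, whose levels were not tested. Plants drifting out of step within a sample would give the same flattening as weaker rhythms in each plant; this was not tested.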

How the results depend on the processing

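Chosen after the data were seen were the omission of single time points and of F. robusta means of unusual composition (LL2 ZT04, LL2 ZT08, LL2 ZT20 and LL3 ZT00, or LD2 ZT12 and ZT16). TMM factors gave 5532 and 5667 rhythmic genes in LD in F. bidentis and F. robusta, 556 genes for light at night in F. robusta, 273 for its species difference, and 136 and 492 for rhythms differing between regimes in F. bidentis and F. robusta. A minimum of 2-fold left 1916 and 2126 genes with different levels in LD and LL, 392 and 157 for light at night and 84 for its species difference, as a stricter rule must. Regime differences in F. bidentis were 184 with a mean of at least 5 RPM, 662 without the trend, 34 with 12 h terms and 3238 with LL from LL1 ZT12 on, and in F. robusta 573 without the trend and 32 with 12 h terms. Without the 4 LL means F. robusta had 0 regime differences and 2676 genes for light at night; without the LD2 pair it had 1302 and 280. With an estimated correlation 4, 1, 2 and 2 lists were called for levels in LD, levels in LL and light at night in F. bidentis and F. robusta. The period difference of -0.25 h became -5.5 h without the trend, -3.25 h after TMM and -0.5 h with a pseudocount of 0.1, and turned to 12.25 h with LL from LL1 ZT12 on, and ASP1 turned to 0.007847 without the LD2 pair. Apart from the 2-fold minimum, the cause was not tested for any of these.

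Leaving out single time points gave 0 to 15 rhythmic genes in F. bidentis LL, 0 to 5 species differences in LL rhythm, 131 to 2676 genes for light at night in F. robusta, 86 to 218 for its species difference, and 661 to 6046 regime differences in F. robusta. Regime differences in F. bidentis ran from 0 to 1844: without LD1 ZT00, ZT04, ZT08, ZT12 and ZT20 they were 37, 22, 104, 10 and 28, without LD2 ZT00, ZT08, ZT12, ZT16 and ZT20 33, 36, 30, 22 and 25, and without LL1 ZT04 to ZT20 610, 537, 308, 1 and 19. Without LL2 ZT00 to ZT20 they were 18, 1, 30, 25, 14 and 27, and without LL3 ZT00 19. The cause was not tested. No paired analysis was possible because the columns used carry no replicate numbers; fits without replicate 1 or 2, a replicate block and a second count-based tool were not run for the same reason.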

Other observations

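The comparisons with LD hours, the daylight hours of LL and the look at single means described here were chosen after the data were seen. In the heat and wound list 4 of 7 genes were rhythmic in F. bidentis and 3 in F. robusta (6 and 3 adjusted over the list alone), among them the chaperone gene HSP90.1 (2.81 and 1.46 log2 units) and the jasmonate repressor gene JAZ1 (2.30 in F. bidentis). In the guard cell list 5 and 5 of 5 genes were rhythmic (4 and 3 after TMM), with the kinase gene OST1 peaking at 12.6 and 12.8 h. In the vascular list 3 and 4 of 8 were (7 and 3 after TMM), with the sucrose transporter gene SUC2 peaking at 13.9 and 13.6 h. Of dividing cell genes, 0 of 3 by limma and 2 were rhythmic (CYCB1.1 and KNOLLE in F. robusta), and SAG12, the measured senescence gene, spanned 2.51 log2 units in F. robusta and 0.27 in F. bidentis, where it did not pass. Between the species the rhythms of FAMA, a guard cell factor, SWEET11, a sucrose exporter, and SAG12 differed, while 0 heat or dividing cell genes did.

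In LD the heat shock factor gene HSFA2 stood higher in F. bidentis by 1.35 log2 units and HSP101 differed by -1.13; the heat list had 2 genes higher and 2 lower, with a median of -0.23 and a mean of -0.02 (2 and 3 in LL). The vascular list had 2 higher and 5 lower in LD and in LL (2 and 3 after TMM in LL), led by the proton pump gene AHA3 (-0.97) and the cellulose synthase gene CESA8 (-0.52). Guard cell genes split 1 and 1 (OST1 0.23, HT1 -0.21; 0 adjusted over the list alone) and 1 and 1 in LL, dividing cell genes 2 and 0 (KNOLLE 1.04) and 3 and 0, and SAG12 was higher by 1.88 and 1.51. By camera none of these lists was called in either regime. The dark and starvation list had 3 genes higher in LL, against 7 in LD.

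In light at night 4 of 7 dark and starvation genes were lower in F. bidentis (5 genes passed adjusted over the list alone): MCCA, and DIN10 by -1.35, SEN1 by -1.70 and DRM1, a dormancy gene, by -2.33 log2 units. Camera did not call the list (adjusted p = 0.191, 0.526 with an estimated correlation, 0.0415 after TMM), while fry called it lower (adjusted p = 0.00018). After TMM BCKDHA was higher, against the list. In F. robusta 0 genes of the list passed by limma, 4 adjusted over the list alone. In the heat list 1 gene rose and 3 fell in F. bidentis, JAZ1 by 1.17, and HSP17.6II fell by 3.27 in F. robusta, which was lost after TMM. The heat list in F. robusta had a camera adjusted p = 0.205 (0.595 with an estimated correlation, 0.0492 after TMM). The mean log2 level of the heat list was high at ZT12 of each LD day, with 7.21 and 7.38 in F. bidentis and 6.77 and 6.49 in F. robusta, against 5.18 and 4.78 at LL1 ZT12. This signal lies in 1 of the 3 hours of each light-at-night comparison, and a fit without ZT12 was not made. Guard cell (2 in F. bidentis, 1 in F. robusta) and vascular genes (2 and 1) were lower as deposited and 0 after TMM, as was RVE1 of the clock outputs in F. bidentis (1 gene; 0 in F. robusta), while dividing cell and senescence genes gave 0 by limma. Between regimes the F. robusta rhythm changed for 3 heat, 3 guard cell, 2 dividing cell, 2 Calvin-Benson, 2 photorespiration, 2 cyclic electron flow, 6 starch, 1 dark response, 1 flavonoid (HY5) and 1 vascular gene, and for 0 senescence genes. After TMM these were 2 heat, 0 guard cell, 0 dividing cell, 2 Calvin-Benson, 1 photorespiration, 1 cyclic electron flow, 1 starch, 0 dark response, 1 flavonoid and 0 vascular. In F. bidentis 0 genes of the heat, guard cell and vascular lists passed by limma (4, 3 and 2 adjusted over the list alone).

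Across genes, which are not independent replicates, each of 26 LL time points was correlated with the LD hours after TMM. At ZT00, ZT04 and ZT08 of LL day 1 the leaves resembled the same LD hour (Pearson's r = 0.939, 0.869 and 0.928 in F. bidentis), and at ZT16 and ZT20 they hardly did (r = 0.264 and 0.091 in F. bidentis, 0.297 and 0.231 in F. robusta). On LL day 2 the highest r lay between 0.168 and 0.284 in F. bidentis. At ZT00, ZT04 and ZT08, LL day 1, which followed an LD night, called 0 genes in either species by limma (254 and 747 at unadjusted p under 0.05). LL day 2, which followed a lit night and so differed from LD in light history, called 454 in F. bidentis (410 after TMM) and 2717 in F. robusta (1295 after TMM). In F. robusta 2432 of these were higher with a median shift of all genes of 0.30 log2 units, and LL2 ZT04 and LL2 ZT08, 2 of its 3 LL means, are among those of unusual composition, so its count may reflect those means.

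A group of 6 F. robusta means was set apart by composition: the TMM factor was 1.23, 1.25, 1.201 and 1.29 at LL2 ZT04, LL2 ZT08, LL2 ZT20 and LL3 ZT00 and 1.31 and 1.36 at LD2 ZT12 and ZT16, and the 10 most abundant genes held 8.26 to 10.5% of reads there against 11.9 to 20.4% in the other F. robusta means. The factor alone does not separate LL2 ZT20 from F. robusta LD1 ZT20 (1.19). Means of F. bidentis at hours dark in LD came near the 4 LL means, such as a factor of 1.27 at LD1 ZT16 and a share of 9.43% at LD2 ZT12. The LD2 pair was taken at hours dark in LD too, but had the highest factors and the lowest shares (8.26 and 8.40%) of all means. The 6 means were kept, and results without them are given with the alternatives.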
